A study of Mus musculus with 6 samples.

How the data were processed

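Total RNA of mouse bone-marrow-derived macrophages, 1 ug per library, was sequenced in 6 libraries: IL4 alone and IL4 with each of 5 compounds, 1 library per treatment. Per the file headers, the deposited tables give for each gene an estimated count (expected count) that is not scaled between libraries; between 30.5% and 32.0% of the values of a library are not whole numbers. The deposited tables also give FPKM, per the file headers, which the authors scaled to transcript length and library size. The submitters' processing notes name HISAT2, Bowtie2, RSEM 1.2.12 and DESeq2 without saying which step each served, and the strand setting is not given in the sources used here. Genes carry NCBI Gene IDs on the GRCm38 assembly. The coordinates in the tables are rounded to 3 digits, so positions were taken from the RefSeq annotation of that assembly, which held 99.3% of the IDs. Genes of the mitochondrial genome were not analysed here.

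Counts were rounded to whole numbers, scaled with TMM factors over the 6 libraries (edgeR 4.0.16 in R 4.3.3), and expressed as the log2 ratio of each compound library to the IL4 library with a prior count of 2. Genes with a CPM (count scaled to library size) of at least 1 in at least 1 library were compared, which left 11898. Library totals ranged from 20181396 to 21169667 counts, so that 3 counts, the floor used for genes at 0, correspond to between 0.137 and 0.161 CPM. Exact Clopper-Pearson 95% intervals of each ratio cover counting error only. A gene was called higher or lower when its log2 ratio was at least 1 in size and its interval excluded no change. With 1 library per treatment no test between treatments was run.

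Gene lists for pathways and cell types were fixed in advance, 31 in all, and 28 had the 3 measured members required for a median. Each median has an order-statistic 95% interval over members and a place among 10000 random lists matched in 20 bins of mean expression. For lists of 3 or 4 measured members the interval is the range of the members, and its coverage is below 95%. Named genes follow a fixed rule: in each comparison the 10 highest and 10 lowest ratios among genes with a regular symbol, at least 50 counts and a CPM of at least 5 in either library and an interval that excludes no change; the 4 members of each list with the largest ratios in size among those with a CPM of at least 5; and 12 genes for every comparison. The text leaves out some genes that the rule names, and the genes named as shared by all 5 comparisons were chosen after their values were seen. These lists, the naming rule, the size rule, the expression filter and the alternatives were set before the data were examined. The minimum of 3 members, the simulated spreads given next and a correction for GC content and transcript length in 20 bins each were chosen afterwards.

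Compounds were compared by the correlation of their ratios across genes, by shared genes, and by the median over list members of the ratio between 2 compound libraries, for 10 pairs. Because all ratios share the IL4 library, 100 sets of 6 unchanged libraries were simulated with spreads between cultures of 0, 10 and 20%. They were drawn from the mean of the 6 libraries, and in each set a simulated control took the place of the IL4 library. The procedure was tested on simulated data with 200 changed genes: in the fatostatin comparison it recovered 100% of genes at a log2 fold of -2 without spread and 96% at a spread of 20%. At that spread it recovered 82% at a log2 fold of -1.5 and called 270 unchanged genes, and the counting intervals covered the true fold of only 24 to 54% of changed genes. The 7 alternatives set in advance were DESeq2 1.42.0 size factors, library totals, no filter, a CPM of at least 5, prior counts of 0.5 and 10, and log2(FPKM + 1); the cholesterol synthesis and alternative activation lists were also summarised by the mean and against the median of the 6 libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 was used for all other steps.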

Results

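Bone marrow cells of C57BL/6 mice were grown for 5 days with 10 ng/ml M-CSF, the growth factor that turns them into macrophages, and the resulting bone-marrow-derived macrophages were treated for 24 hours. One culture condition received IL4, the cytokine that drives alternative activation of macrophages. The other 5 received IL4 together with fatostatin, betulin, 25-HC, PF429424 or 1,10-Phen, at doses the labels do not give. No library without IL4 is among them, so these data do not show which genes IL4 induced in these cells. A lower ratio of an alternative activation gene is therefore not by itself a loss of the IL4 response. Fatostatin and betulin are known as blockers of the processing of SREBP transcription factors, which switch on genes of cholesterol and fatty acid synthesis. The labels expand neither 25-HC nor 1,10-Phen and give no target for any of the 5 compounds, so no relation of 25-HC, PF429424 or 1,10-Phen to SREBP is assumed here. The series title names SREBP2, alternative activation and allergic airway inflammation, so the comparisons ask how each compound altered the transcriptome of IL4-treated macrophages, with the genes of cholesterol synthesis and of alternative activation first.

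RNA sequencing gave 1 library per treatment, 6 in all, and the 6 libraries held between 20181396 and 21169667 estimated counts. Because no treatment was repeated, no difference reported here has a replicate check, and no p-value is given. Each value compares 2 libraries, not 2 conditions. Intervals of single genes are exact 95% counting intervals, cover counting error only, and say nothing about variation between cultures. List medians are placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Random lists were drawn gene by gene, so their members need not vary together as members of a pathway may. An extreme place among them is therefore no measure of significance.

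The libraries stood at graded distances from the IL4 library. The rank correlation with it across genes was 0.993 for fatostatin, 0.985 for betulin, 0.974 for PF429424, 0.969 for 25-HC and 0.926 for 1,10-Phen. Correlations with the fatostatin library were higher: 0.990 for betulin, 0.982 for PF429424, 0.975 for 25-HC and 0.932 for 1,10-Phen. A deviation of the IL4 library and a difference shared by the compound libraries cannot be told apart from these values. Of 11898 genes compared, 230 differed at least 2-fold beyond counting error in the fatostatin library, 499 in the betulin library, 966 in the PF429424 library, 1066 in the 25-HC library and 2311 in the 1,10-Phen library. In 100 simulations of unchanged libraries, an assumed spread of 10% between cultures gave at most 59 such genes in any comparison and a spread of 20% gave at most 346. The fatostatin count lies below 346, and the counts of the other 4 libraries lie above it.

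**Figure D1:**
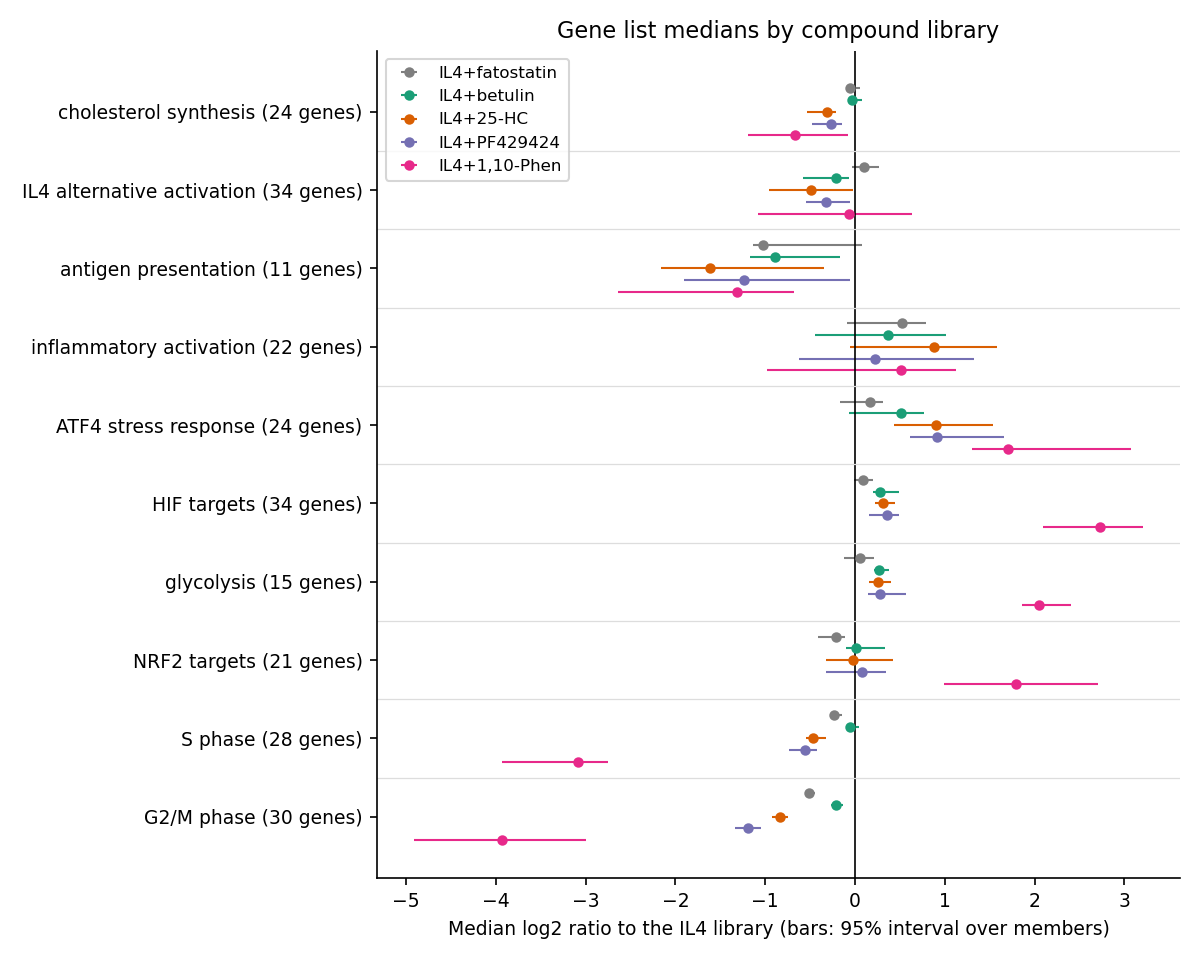
Median log2 ratio to the IL4 library (x axis) of 10 gene lists (y axis) in the 5 compound libraries, with the 95% interval of the median over list members. Cholesterol synthesis genes sit between -0.67 and -0.029, and the G2/M list reaches -3.93 in the 1,10-Phen library.

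In the fatostatin library, genes of cholesterol synthesis were close to their level with IL4 alone, while 6 of 11 antigen presentation genes were at least 2-fold lower. The 24 cholesterol synthesis genes had a median log2 ratio of -0.052, or 0.12 when the median of the 6 libraries replaced the IL4 library as reference, and none differed 2-fold. Stard4, a sterol carrier, was at -0.40 and Srebf2 itself at -0.03. The alternative activation list of 34 genes had a median of 0.10, above those of 9901 of the 10000 random lists. Its interval over members, -0.028 to 0.27, held 0, and no member was at least 2-fold higher and 1 was lower. Its best known members were split, since Arg1 (arginase) was at 0.53, Chil3 (a chitinase-like protein) at 0.70 and Mrc1 (the mannose receptor) at 0.26, whereas Retnla (a resistin-like protein) was at -0.57. Ptgs1, which encodes a cyclooxygenase, had the lowest ratio of the list at -1.68.

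Rankings of ratios are given here among genes with a regular symbol and, in either library, at least 50 counts and a CPM of at least 5, since other genes reached higher ratios. By that rule the highest ratios with fatostatin were those of Bex1 (2.84, interval 2.61 to 3.10), Mt2, a metallothionein (2.12), Cnrip1 (1.60), Htr2b, a serotonin receptor (1.53), Gprc5b (1.45) and Dio2, a deiodinase that activates thyroid hormone (1.39). Among the lowest were Ahrr, the repressor of the aryl hydrocarbon receptor (-2.69, interval -2.96 to -2.46), Nqo1, a quinone oxidoreductase (-2.18), and Cyp1b1, a cytochrome P450 (-1.74). Ly6a was at -2.73, Gpr141 at -2.55, Mmp8, a collagenase, at -2.45 and Vcan, which encodes versican, at -2.36. Nqo1 belongs to the list of targets of NRF2, the oxidative stress regulator. That list had a median of -0.21 (interval over members -0.41 to -0.11), below all random lists. Of its 21 members 17 were below 0 and 4 above, and 1 was at least 2-fold lower. The antigen presentation list of 11 genes, most but not all of the MHC class II pathway, had a median of -1.02, below all random lists, and 6 members were at least 2-fold lower, with Ciita, the transactivator of MHC class II genes, at -1.61 and H2-Aa at -1.09. Genes of the G2/M phase were lower as a group, with a median of -0.51 over 30 genes and none past 2-fold; Top2a was at -0.66 and Cenpf at -0.65. The neutrophil marker list had a median of 0.28 (interval over members -0.66 to 0.53), above 9984 of 10000 random lists. The inflammatory list of 22 genes had a median of 0.52 (interval over members -0.086 to 0.79), above all random lists, and 2 members were at least 2-fold higher, among them the chemokine gene Ccl7 at 1.2. The list of lipid droplet and fatty acid oxidation genes had a median of 0.14, with 2 of 22 members at least 2-fold higher and 5 below 0. The higher members were the fatty acid binding protein gene Fabp4 at 1.22 and Hilpda, a lipid droplet protein, at 1.21. The zinc finger gene Zfp967 held 0 counts with fatostatin and 178 with IL4 alone, at least 58.7-fold lower against a floor of 3 counts per library, but it lies in a zinc finger cluster of 27 genes of which 8 held 0 counts in at least 1 library and at least 50 in another, and its value is uncertain. With fatostatin 104 genes were at least 2-fold higher and 126 lower, against 150 and 144 in simulated unchanged libraries at a spread of 20%. With log2(FPKM + 1) as the unit the split was 23 higher and 47 lower, and among genes with a CPM of at least 5 it was 42 and 64.

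In the betulin library, the metallothionein gene Mt2 had the highest ratio of the named genes, and 3 alternative activation genes were at least 2-fold lower, while cholesterol synthesis genes stayed near their level with IL4 alone. Mt2 had a log2 ratio of 6.30 (interval 5.93 to 6.85; 3451 counts against 42) and Mt1 of 2.73. Slc30a1, a zinc exporter, was at 1.39 and Slc39a10, a zinc importer, at -1.62. Of the 12 genes of metal response 3 were at least 2-fold higher and 2 lower, with a median of 0.36 (interval over members -0.73 to 1.39). The alternative activation list had a median of -0.21, below all 10000 random lists, or -0.051 against the median of the 6 libraries, and 3 of 34 members were at least 2-fold lower. Retnla was at -1.67 (interval -1.73 to -1.62), the chemokine gene Ccl24 at -1.54 and Fn1, fibronectin, at -1.31, while Mrc1 was at -0.72 and Arg1 and Chil3 at -0.12 and -0.20.

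The cholesterol synthesis median with betulin was -0.029, with 4123 of 10000 random lists below it, the mean was 0.013, the median against the median of the 6 libraries was 0.11, and no member differed 2-fold. Stard4 was at -0.42, Fdps at 0.40, Sqle at 0.31 and Srebf2 at -0.03. The 8 stromal marker genes had a median of -0.59, with the collagen genes Col1a1 at -1.61 and Col1a2 at -1.53. Of 22 macrophage identity genes 2 were at least 2-fold lower, Cx3cr1, the fractalkine receptor (-1.97), and Maf, a transcription factor (-1.32), and the chemokine receptor gene Ccr2 was at -2.02. Hpgd, the enzyme that degrades prostaglandins, was at -3.06. The antigen presentation list was at -0.89, below all random lists, with 4 of 11 members at least 2-fold lower and Cd74, the invariant chain, at -1.17. The inflammatory list had a median of 0.37 (interval over members -0.44 to 1.01), and 6 of 22 members were at least 2-fold higher, among them the chemokine genes Cxcl2 at 2.44, Ccl7 at 1.75 and Ccl2 at 1.52. Efcc1 (3.91), Rtn4r, the Nogo receptor (3.29), Dio2 (3.22) and Gprc5b (2.69) were among the 10 highest ratios by the same rule. The ATF4 list, made of genes of the integrated stress response, had a median of 0.52, above all random lists, with 4 of 24 members at least 2-fold higher, among them Trib3 at 1.45 and Asns, asparagine synthetase, at 1.05. The neutrophil marker list had a median of 0.49, with S100a8 at 1.13 and Csf3r at -1.12. Zfp966 held 0 counts with betulin and 244 with IL4 alone, at least 80.8-fold lower, and is uncertain because it lies in the same cluster as Zfp967. With betulin 227 genes were at least 2-fold higher and 272 lower; with log2(FPKM + 1) as the unit these were 76 and 101.

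**Figure D2:**
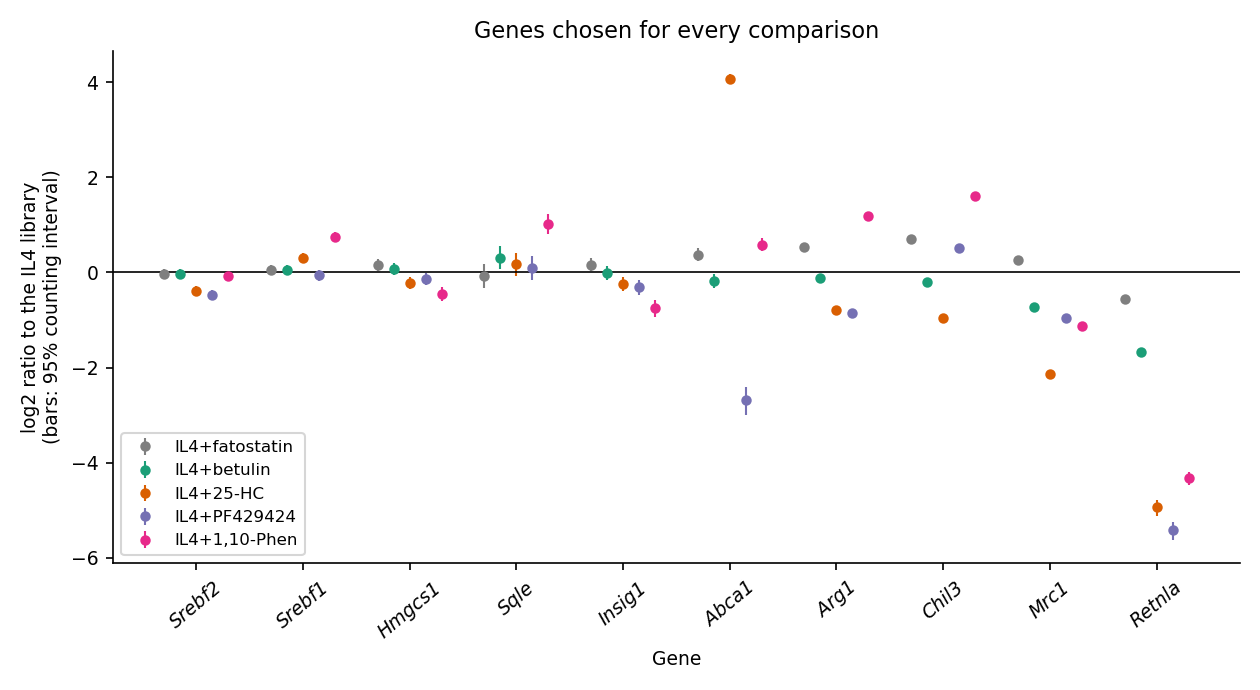
Log2 ratio to the IL4 library (y axis) of 10 genes chosen for every comparison (x axis), coloured by compound, with 95% counting intervals as bars. Retnla lies between -5.42 and -0.57 and Abca1 between -2.68 and 4.06.

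In the 25-HC library, 3 of 11 LXR target genes, among them cholesterol exporters, and 4 of 15 genes of fatty acid synthesis were at least 2-fold higher. Genes of cholesterol synthesis had a median below 0, and 10 of 34 alternative activation genes were at least 2-fold lower. Abca1, a cholesterol exporter, had a log2 ratio of 4.06 (interval 3.96 to 4.17; 13252 counts against 775), the exporter Abcg1 of 2.45 and Mylip, a ubiquitin ligase, of 1.73. The desaturase genes Scd2 and Scd1 were at 4.66 and 3.11, Acaca, acetyl-CoA carboxylase, at 1.29, Fasn, fatty acid synthase, at 1.13 and Srebf1 at 0.31. The fatty acid synthesis list had a median of 0.12 (interval over members -0.32 to 1.13), with 7 members below 0 and 1 at least 2-fold lower. The LXR target list of 11 genes had a median of -0.24 and a mean of 0.41, which differ in sign, since 3 members were at least 2-fold higher and 2 lower, with Apoc2 at -1.33.

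The cholesterol synthesis list had a median of -0.32 (interval over members -0.53 to -0.21), below 9966 of 10000 random lists, or -0.15 against the median of the 6 libraries, and 3 of 24 members were at least 2-fold lower, among them Stard4 at -1.51. Srebf2 was at -0.39 and Insig1, an SREBP retention factor, at -0.24, while Sqle was at 0.17. Of the 34 alternative activation genes, 10 were at least 2-fold lower and none higher, and the median of -0.48 lay below all random lists. Retnla was at -4.94 (interval -5.11 to -4.79; 335 counts against 10103), Ccl24 at -4.13, Pdcd1lg2, the gene of a checkpoint ligand, at -2.62, Tfrc, the transferrin receptor, at -2.30, Mrc1 at -2.13, Chil3 at -0.96 and Arg1 at -0.79. Other genes with very low ratios were Scn3a, a sodium channel (-5.76), the purinergic receptor gene P2ry12 (-4.47), Hpgd (-4.43), Cbr2 (-4.42), F13a1, the coagulation factor subunit (-3.85), and Cd163, the haemoglobin scavenger receptor (-3.76).

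Of 22 macrophage identity genes 9 were at least 2-fold lower with 25-HC and 1 higher, with Maf at -2.68 and the complement gene C1qa at -2.12. Markers of other cell types differed as well: the 8 stromal genes had a median of -0.61 (interval over members -1.21 to 0.16), below 9807 of 10000 random lists, and the 13 neutrophil genes of 0.40 (interval -0.21 to 1.04), above 9960 of them. The antigen presentation list was at -1.61, with 7 of 11 members at least 2-fold lower and Ciita at -2.89. The ATF4 list had a median of 0.90 with 10 of 24 members at least 2-fold higher, including Trib3 at 3.50, Chac1 at 3.46 and Mthfd2 at 1.77. The inflammatory list was at 0.88 (interval over members -0.054 to 1.58), with 10 of 22 members at least 2-fold higher and 2 lower, and with Il1a at 2.26 and Tnf at 1.68. Mmp13, a collagenase, was at 2.01, Vegfa at 1.83 and Plin2, a lipid droplet coat protein, at 1.28. Efcc1 (5.60), Flnc (4.10) and Dio2 (3.70) were among the 10 highest by that rule. The G2/M list had a median of -0.83 with 6 of 30 members at least 2-fold lower, Nuf2 at -1.43 among them. With 25-HC 389 genes were at least 2-fold higher and 677 lower; with log2(FPKM + 1) as the unit these were 174 and 340.

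In the PF429424 library, 11 of 24 genes of the ATF4 stress response were at least 2-fold higher and 9 of 13 neutrophil marker genes were at least 2-fold lower, and the cholesterol synthesis and alternative activation lists had medians below 0. Chac1, a glutathione-degrading enzyme, had a log2 ratio of 4.59, Trib3 of 3.58, Asns of 3.21 (interval 3.08 to 3.36; 4101 counts against 466) and Mthfd2, of folate metabolism, of 2.15. The ATF4 list had a median of 0.91 with 11 of 24 members at least 2-fold higher and none lower. The list of the endoplasmic reticulum unfolded protein response had a median of -0.26, below all random lists, with 3 of 22 members at least 2-fold lower, the endoplasmic reticulum chaperone genes Calr at -1.45, Sdf2l1 at -1.19 and Pdia4 at -1.10, and 1 higher, Dnajb9 at 1.10. The immediate early and heat shock list, which holds other chaperone genes, had a median of 0.33 (interval over members -0.13 to 0.44).

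The cholesterol synthesis list had a median of -0.27 (interval over members -0.48 to -0.14), below 9942 of 10000 random lists, or -0.13 against the median of the 6 libraries, with 3 of 24 members at least 2-fold lower, among them Stard4 at -1.85. Mvd was at -0.71, Srebf2 at -0.48, Insig1 at -0.31 and Sqle at 0.09. The LXR target list had a median of -0.47, with Abca1 at -2.68 (interval -3.00 to -2.41), Mylip at -1.21 and, in the fatty acid list, Scd2 at -1.24. The alternative activation list was at -0.33, below all random lists, with 7 of 34 members at least 2-fold lower. Retnla was at -5.42 (interval -5.63 to -5.24; 222 counts against 10103), Ccl24 at -4.03, Pdcd1lg2 at -1.49, Fn1 at -1.25, Mrc1 at -0.97 and Arg1 at -0.85, whereas Chil3 was at 0.51.

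Neutrophil marker genes were lower with PF429424, with a median of -1.65 over 13 genes and 9 at least 2-fold lower, among them Ltf, lactoferrin (-2.63), Lcn2, lipocalin (-2.47), Camp (-2.17) and Ngp (-1.99). G2/M genes were lower too, with a median of -1.19 and 23 of 30 members at least 2-fold lower, including Aurkb at -1.55 and Plk1 at -1.42. Macrophage identity genes had a median of -0.49 (interval over members -1.81 to 0.091) with 7 of 22 at least 2-fold lower and 15 within 2-fold, with Cx3cr1 at -3.46 and C1qa at -2.56. The antigen presentation list had a median of -1.24 with 7 of 11 members at least 2-fold lower. The inflammatory list had a median of 0.22 (interval over members -0.62 to 1.32), with 7 of 22 members at least 2-fold higher and 2 lower. The metal response list had a median of 0.23 with 1 of 12 members at least 2-fold higher and 2 lower, and its iron genes included Slc40a1, ferroportin, at -2.52 and Fth1, ferritin heavy chain, at 0.82. Gpnmb, the most abundant transcript of this library, was at 1.38, Rbp4, retinol binding protein, at 4.22 and Bex1 at 3.58. By the main scaling 296 genes were at least 2-fold higher and 670 lower; with library totals as the scaling the split was 216 and 871 and the median of all genes moved to -0.11. With log2(FPKM + 1) as the unit the split was 95 and 397.

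**Figure D3:**
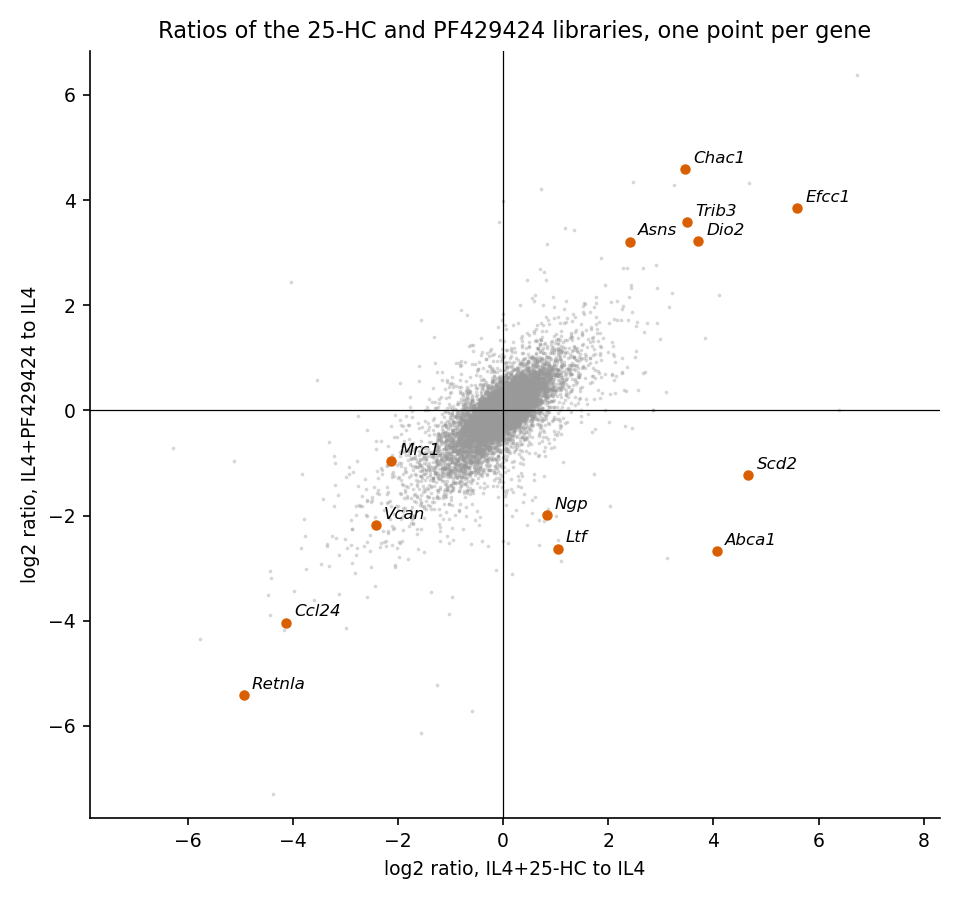
Log2 ratio to the IL4 library in the 25-HC library (x axis) and the PF429424 library (y axis), one point per gene for 11898 genes, with named genes in orange. Retnla is low in both libraries, whereas Abca1 is at 4.06 and -2.68, Scd2 at 4.66 and -1.24 and Ltf at 1.04 and -2.63.

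In the 1,10-Phen library, targets of hypoxia-inducible factor and genes of glycolysis were higher almost throughout, and genes of DNA replication and cell division were lower. Of 34 hypoxia targets 31 were at least 2-fold higher, and the median log2 ratio of 2.73 (interval over members 2.10 to 3.21) lay above all random lists. Egln3, a prolyl hydroxylase, was at 8.94 (interval 8.49 to 9.68; 11529 counts against 25), Ero1l, an endoplasmic reticulum oxidase, at 5.10, Bnip3, a mitophagy receptor, at 4.94 and Ak4 at 4.65. Of 15 glycolysis genes 13 were at least 2-fold higher, with a median of 2.05, Pgk1 at 2.92 and Pfkl at 2.50; 10 genes belong to both lists. Of 30 G2/M genes all 30 were at least 2-fold lower, with a median of -3.93, and of 28 S phase genes 25 were, with a median of -3.09. Ccna2, cyclin A, was at -7.66, Mki67 at -6.80, Cenpf at -6.47 and Rrm2, a ribonucleotide reductase subunit, at -5.78. Pbk held 0 counts against 406, at least 118-fold lower. Much smaller differences of the hypoxia list, with intervals above 0, were present with betulin (median 0.28), 25-HC (0.31) and PF429424 (0.35). With fatostatin its median was 0.091 (interval over members -0.013 to 0.20). Glycolysis medians were 0.27 with betulin, 0.26 with 25-HC, 0.28 with PF429424 and 0.056 with fatostatin.

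Targets of NRF2, the oxidative stress regulator, were higher with 1,10-Phen, 15 of 21 by at least 2-fold, with a median of 1.79, Gsta4 at 5.20, Slc7a11, the cystine transporter, at 4.12 and Hmox1, haem oxygenase, at 3.43. The ATF4 list had a median of 1.71 with 20 of 24 members at least 2-fold higher, Trib3 at 5.47 and Chac1 at 4.64. The unfolded protein response list had a median of -0.44 (interval over members -0.63 to 0.040), below all random lists. Of its 22 members 1 was at least 2-fold lower and 2 were higher. Mt2 was at 6.29 and Mt1 at 2.72, Ptgs2, the inducible cyclooxygenase, at 6.18 and Mmp13 at 3.83. The inflammatory list, which holds Ptgs2, had a median of 0.51 (interval over members -0.98 to 1.12), with 6 of 22 members at least 2-fold higher and 5 lower. Mgarp held 243 counts against 0 with IL4 alone, at least 93.2-fold higher, and Gsta3 was at 6.22.

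The cholesterol synthesis list with 1,10-Phen had a median of -0.67 (interval over members -1.20 to -0.076), below 9988 of 10000 random lists, with 8 of 24 members at least 2-fold lower and 1 higher. Stard4 was at -2.13, Fdps at -1.64, Cyp51 at -1.5 and Insig1 at -0.75, while Sqle was at 1.01 and Srebf1 at 0.75. The alternative activation list had a median of -0.064, which was 0.15 among genes with a CPM of at least 5, and 9 members were at least 2-fold higher and 15 lower. Chil3 was at 1.60 and Arg1 at 1.2, but Retnla was at -4.32 (interval -4.46 to -4.18), Ccl24 at -4.37, Ccl22 at -4.33, Irf4, a transcription factor of alternative activation, at -3.31 and Mrc1 at -1.12. The macrophage identity list had a median of -0.58 (interval over members -1.88 to -0.23), with 7 of 22 members at least 2-fold lower, C1qa at -3.38 among them, and 15 within 2-fold. The antigen presentation list had a median of -1.32 with 7 of 11 members at least 2-fold lower, Ciita at -3.53 among them. Neutrophil marker genes had a median of -2.55 with 9 of 13 at least 2-fold lower, Mpo, myeloperoxidase, at -4.57 among them. By the main scaling 903 genes were at least 2-fold higher and 1408 lower; with library totals the split was 641 and 1940 and the median of all genes moved to -0.25. With log2(FPKM + 1) as the unit the split was 399 and 1201 and that median was -0.19.

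**Figure D4:**
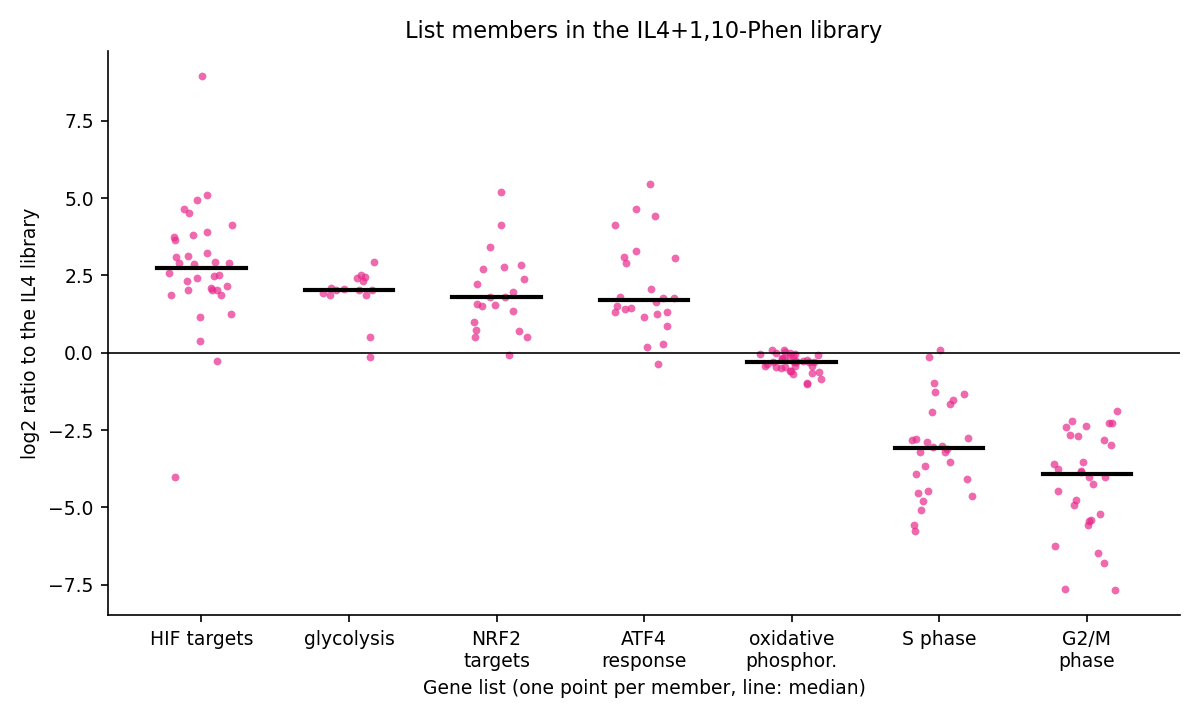
Log2 ratio to the IL4 library (y axis) of the members of 7 gene lists (x axis) in the 1,10-Phen library, one point per gene, with a line at each list median. Hypoxia targets reach 8.94 and G2/M genes lie between -7.66 and -1.87.

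Ratios to the IL4 library were most alike across genes among betulin, 25-HC and PF429424. Pearson r and Spearman rho were 0.716 and 0.699 for 25-HC and PF429424, 0.705 and 0.697 for betulin and 25-HC, and 0.689 and 0.718 for betulin and PF429424, so the 2 measures rank these pairs differently. Genes are not independent replicates, and all 5 comparisons share the IL4 library. Simulated unchanged libraries set against a shared simulated control gave r near 0.50. The covariance was 0.287 for 25-HC and PF429424, 0.222 for betulin and 25-HC and 0.202 for betulin and PF429424. It was larger for 1,10-Phen with 25-HC (0.316; r = 0.461) and with PF429424 (0.304; r = 0.475), where r was lower. Simulated unchanged libraries at a spread of 20% gave 0.098. The covariances of fatostatin with the other 4 libraries lay between 0.091 and 0.112, near that simulated value and above the 0.035 simulated at a spread of 10%. A spread of 20% may be too large for the fatostatin library. It held 104 higher and 126 lower genes, against 150 and 144 in those simulations. The nearness to 0.098 therefore does not show that the fatostatin ratios are those of unchanged libraries. At least 2-fold lower in both the 25-HC and the PF429424 library were 380 genes and 159 were higher in both. Independent calls in the 2 libraries would share 38.1 lower and 9.68 higher genes. Simulated unchanged libraries with a shared simulated control gave 14.8 and 33.9 at a spread of 20%, but they hold fewer calls than these libraries. Lower in the 1,10-Phen library together with the 25-HC or the PF429424 library were 379 and 398 genes, against 14.9 and 14.7 in those simulations. Independent calls would share 80.1 and 79.3, more than for 25-HC with PF429424, since more genes were lower with 1,10-Phen. Between the 25-HC and PF429424 libraries the median difference over the cholesterol synthesis list was -0.0028 (interval -0.21 to 0.15) and over the alternative activation list -0.034 (interval -0.15 to 0.34). The cholesterol list lay lower with 25-HC than with betulin, by a median of -0.34 (interval -0.48 to -0.21), and lower with 25-HC than with fatostatin, by -0.35 (interval -0.54 to -0.17). Doses may differ between compounds and are not labelled, and part of any shared difference may come from the IL4 library.

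In all 5 compound libraries 15 genes were at least 2-fold higher and 28 at least 2-fold lower than with IL4 alone. The total of 43 fell to 27 among genes with a CPM of at least 5, to 27 with a prior count of 10 and to 13 with log2(FPKM + 1). Simulated unchanged libraries sharing a simulated control gave 5 higher and 0.34 lower at a spread of 20%. Dio2 (1.11 to 3.70), Hilpda (1.21 to 3.15), Gprc5b (1.45 to 3.21), Dach1 (1.2 to 1.77) and Ccl7 (1.2 to 1.75) were higher in each library. Ciita (-3.53 to -1.27), Hpgd (-4.61 to -1.02), Sema6d (-3.02 to -1.82), Ahrr (-2.69 to -1.31), Ccr2 (-2.70 to -1.11), Cx3cr1 (-3.46 to -1.07) and the guanylate-binding protein gene Gbp3 (-2.14 to -1.57) were lower in each. These genes were chosen for naming after their values were seen. Of the 43 genes 7 held 0 counts in at least 1 library, Hmga1b, Zfp973, Gm14308, Gm42078, Npcd, Apol7c and Adgre4, and the sizes of their ratios are uncertain. Zfp973 and Gm14308 lie in the zinc finger cluster that holds Zfp966 and Zfp967, so whether they were lower at all is uncertain too. The IL4 library cannot be split, so a deviation of that library would move all 5 ratios of a gene together.

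On the GRCm38 assembly, Retnla (NCBI gene 57262) lies on chromosome 16 from 48842609 to 48844461 and Ciita (12265) on the same chromosome from 10480014 to 10531064. Abca1 (11303) lies on chromosome 4 from 53030789 to 53159988. Srebf2 (20788) lies on chromosome 15 from 82147269 to 82205379, Egln3 (112407) on chromosome 12 from 54178981 to 54203874 and Mt2 (17750) on chromosome 8 from 94172618 to 94173567. All 6 are annotated as protein coding, and counts cover whole genes, without separating exons or untranslated regions.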

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

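The correction for GC content and length was a test chosen after the result was seen; the other alternatives were planned. No paired analysis was possible because each treatment has 1 library, and for the same reason no library could be left out. Depth limits genes near 3 counts, where intervals are wide, and no setting measures the variation between cultures. Across the alternatives 1071 list medians stayed within their interval, 45 moved beyond it without being counted as reversed, and 9 reversed. Reversed means here that the sign changed where the interval over members excluded 0. Counting every change of sign, also of medians whose interval holds 0, 50 of these values changed sign, over all settings. Of the counts of genes called higher, 31 stayed within 1.5 times and 9 did not, and the same numbers held for genes called lower. Of the counts in all 5 comparisons 5 stayed and 3 did not, and all 80 correlations across genes stayed within 0.1. Among the values of named single genes 2178 stayed within their counting interval, 350 moved beyond it and none reversed. Fewer genes were compared with the stricter filter and more without a filter, and the larger prior count and the added 1 in log2(FPKM + 1) shrink ratios of low values by construction. For every other value below the cause was not tested.

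Without a filter 166 genes were higher with fatostatin. The median of the dendritic markers was then -0.59 with betulin and -0.73 with PF429424, and that of the erythroid markers -0.28 with 25-HC and -0.20 with PF429424. The median of the T and NK cell markers with fatostatin reversed from 0.30, over only 4 genes in the main setting, to -0.47. With a CPM of at least 5, 42 genes were higher with fatostatin and 138 with betulin, 64 were lower with fatostatin, 146 with betulin, 442 with 25-HC and 435 with PF429424, and 27 passed in all 5 comparisons. With a prior count of 10, 52 genes were higher and 76 lower with fatostatin, and 27 passed in all 5.

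With log2(FPKM + 1), 23 genes were higher with fatostatin, 76 with betulin, 174 with 25-HC, 95 with PF429424 and 399 with 1,10-Phen. Lower were 47 with fatostatin, 101 with betulin, 340 with 25-HC and 397 with PF429424, and 13 passed in all 5. List medians in this unit were -0.098 with fatostatin and -0.085 with betulin for cholesterol synthesis, 0.19 with betulin for hypoxia and 0.10 with fatostatin for T and NK cell markers. With 1,10-Phen they were -0.65 for the unfolded protein response, 1.14 for ATF4 and -0.22 for the lysosome. The S phase median was -0.11 with betulin and -2.59 with 1,10-Phen, and that of glycolysis 0.20 with betulin, 0.14 with PF429424 and 1.79 with 1,10-Phen. Oxidative phosphorylation was at -0.045 with fatostatin, 0.030 with betulin and -0.53 with 1,10-Phen, and reversed to -0.066 with PF429424. Ribosomal protein genes were at -0.14 with fatostatin and -0.043 with betulin, and reversed to -0.031 with PF429424 and -0.13 with 1,10-Phen.

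With library totals the cholesterol synthesis median was -0.11 with fatostatin and -0.094 with betulin. With 1,10-Phen the interferon median was -0.86, that of the unfolded protein response -0.69 and that of the lysosome -0.23. S phase was at -0.29 with fatostatin and -0.12 with betulin, G2/M at -0.57 and -0.28, and glycolysis at 0.20 with betulin, 0.15 with PF429424 and 1.80 with 1,10-Phen. Oxidative phosphorylation was at -0.054 with fatostatin, 0.036 with betulin and -0.54 with 1,10-Phen, and reversed to -0.072 with PF429424. Ribosomal protein genes were at -0.14 with fatostatin and -0.037 with betulin, and reversed to -0.032 with PF429424 and -0.13 with 1,10-Phen.

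With the median of the 6 libraries as reference the cholesterol synthesis median was 0.12 with fatostatin, 0.11 with betulin, -0.15 with 25-HC and -0.13 with PF429424, and that of alternative activation -0.051 with betulin. After the GC and length correction the oxidative phosphorylation median reversed to -0.0065 with betulin and -0.023 with PF429424, and that of ribosomal protein genes was -0.072 and 0.0054.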

Other observations

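The comparison of the 25-HC and PF429424 libraries with the fatostatin library, the use of library totals for the hypoxia list, the medians outside glycolysis and the effect of losing zinc finger members at 0 were tests chosen after the result was seen.

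The 23 interferon-stimulated genes had a median log2 ratio of -0.62 with 1,10-Phen, below 9978 of 10000 random lists, and of -0.51 with 25-HC and -0.35 with betulin, below 9997 and 9998 of them, and of 0.14 with fatostatin. With PF429424 the median was 0.022, or -0.12 with library totals, and 6 members were at least 2-fold higher, among them Rsad2 (viperin) at 1.71. Lysosomal genes had a median of 0.19 with fatostatin and 0.33 with PF429424, where the cathepsin gene Ctsd was at 0.92. The 19 p53 targets had a median of -0.23 with 1,10-Phen, with 5 at least 2-fold higher and 2 lower, and of -0.16 with 25-HC, with 3 higher and 3 lower. Among them Gadd45a, a stress-induced growth regulator, was at 3.18 with 1,10-Phen and 1.86 with 25-HC, while Sesn1, a sestrin, was at -2.24 and -2.11.

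Nuclear genes of oxidative phosphorylation had a median of -0.30 over 36 genes with 1,10-Phen, with 1 member at least 2-fold lower, Ndufs8 at -1.01. Ribosomal protein genes had a median of 0.11 with 1,10-Phen, or -0.13 with library totals, and 1 of 32 members, Rpl3, stood at -1.55. Gata2, a transcription factor of mast cell precursors, was at 2.25 with 25-HC and 1.71 with PF429424.

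A set of 380 genes was at least 2-fold lower in both the 25-HC and the PF429424 library, with a median log2 ratio of -1.60 to the IL4 library, averaged over the pair. Set against the fatostatin library instead, the median was -1.19 (interval -1.26 to -1.10), which argues against a deviation of the IL4 library alone. The median was smaller in size than against IL4, so a partial contribution of the IL4 library stays open. After removal of the trend over GC content and length, 95.9% (exact interval 93.3 to 97.7) of the 366 genes with annotation stayed at -1 or below in both, which argues against that trend as the whole cause. Genes lower with 1,10-Phen together with 25-HC or PF429424 numbered 379 and 398. Independent calls would share 80.1 and 79.3 of them, against 38.1 for 25-HC with PF429424. With 1 library per treatment, a response to the compounds and a difference in handling between cultures both stay open, and neither was tested.

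Of 34 hypoxia targets 31 were at least 2-fold higher with 1,10-Phen, and the list median was 2.49 with library totals (interval 1.86 to 2.97). A change of scaling moves all genes by nearly the same amount, set here by the TMM factors. It is therefore no independent test of a shift of scale by a few abundant genes. With library totals the median of all genes was -0.25, far below that of the list. The list median was 2.76 after the GC and length correction (interval 2.14 to 3.23). The 24 members outside the glycolysis list had a median of 3.10 (interval 2.49 to 3.90), so the difference was not limited to glycolytic members. A response to the compound and a difference in culture conditions such as oxygen both stay open, and neither was tested.

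In a zinc finger cluster of 27 genes on chromosome 2, between 175016710 and 178078425, 8 members held 0 counts in at least 1 library and at least 50 in another. The highest count of each of these members lay between 158 (LOC102633156, IL4 library) and 545 (Gm4724, 25-HC library), against 0 in another library. Library totals were similar, between 20181396 and 21169667 counts. Gaps of that size argue against sampling noise alone for these 8 members, although they were chosen for such counts. Division of reads between near-identical copies may underlie the on and off values of Zfp966 and Zfp967, but read assignment was not tested directly. The summed counts of the cluster differed from the IL4 library by at most 0.14 on the log2 scale, but loss of all 8 members would move the sum by only -0.27, so the sum does not decide. A real difference in expression stays open as well.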
